A study of Mus musculus and Homo sapiens with 22 samples.

How the data were processed

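RNA of MDA-MB-231 and 4T1 cells, plated 24 h before a 24 h treatment, was sequenced in 22 libraries, 10 of MDA-MB-231 and 12 labelled 4T1. The authors deposited 1 table of raw read counts per gene for each library, and every value was checked to be a whole number that is not negative. The submitters' processing notes name FastQC 0.11.3, Bowtie, TopHat, HTSeq and DESeq2 and the builds hg38 and mm10. The versions of the other tools, their order, the annotation and the counting strand are not given in the sources used here, so counts of overlapping or antisense genes are uncertain. Each MDA-MB-231 library listed 42713 gene IDs and each 4T1 library listed 38924. Of the 4T1 IDs 37607 matched the GENCODE mouse release 21 name table (GRCm38, the same assembly as mm10) when ID versions were ignored, and coordinates are from that table. No human name table was used here, so MDA-MB-231 genes were not named and the gene lists, named genes and the difference between the cell lines were not analysed here. The growth protocol gives 1 or 2 µM ENMD-2076 for 4T1 where the treatment labels and the design text give 1.25 or 2.5 µM, and the latter were used. Column headers of the 4T1 ENMD-2076 tables read 4T1_1_10uM in the pair labelled 1.25 µM and 4T1_2_10uM in the pair labelled 2.5 µM, and name no compound, whereas those of MDA-MB-231 name compound and dose as labelled. The labels were followed.

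Groups were compound and dose as labelled. The 4T1 tables came in 2 naming sets, 1 with ENMD-2076 and DMSO 1 and 2 and the other with TAK901 and DMSO 3 and 4, and naming set was a term of every 4T1 fit. Tables of set 2 ended in HTSeq summary lines, which were removed from the counts. As a percent of all records, those lines gave 8.27 to 12.0 aligned to several places, 5.51 to 7.63 in no feature, 1.82 to 2.50 ambiguous and 1.61 to 2.17 of low alignment quality. They gave 26.7 and 20.0 not aligned in DMSO 3 and 4, 40.1 and 16.4 with 1 µM TAK901, and 19.0 and 20.8 with 2 µM. Totals of the gene counts were 13.4 and 16.0 M reads for MDA-MB-231 DMSO, 24.0 and 13.8 for ENMD-2076 2.5 µM, 13.5 and 23.9 for 5 µM, 14.1 and 14.3 for TAK901 1 µM, and 13.9 and 14.9 for 2 µM. For 4T1 they were 18.6, 17.2, 22.1 and 24.8 M reads for DMSO, 14.4 and 30.9 for ENMD-2076 1.25 µM, 20.7 and 14.4 for 2.5 µM, 15.9 and 27.1 for TAK901 1 µM, and 6.00 and 3.75 for 2 µM. A floor of 3 reads per library, the upper 95 percent limit of a count of 0, stood at 0.500 and 0.801 CPM in the last pair and at 0.0972 to 0.208 CPM in the other 4T1 libraries. Folds against groups without reads used this floor and cover counting error only.

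Differential expression was tested with edgeR 4.0.16 under R 4.3.3: filterByExpr, TMM scaling, and a quasi-likelihood fit of all groups of a line, with 14826 genes tested in MDA-MB-231 and 15375 in 4T1. Two-sided p-values were adjusted by Benjamini-Hochberg over the genes tested, with 0.05 as the threshold. SE was derived from the test, as the size of the log2 fold change over the square root of its F statistic. Levels are TMM-normalised CPM, as mean ± SD over the 2 libraries of a group. Gm26917 and Gm42418 are the exception, given per library as CPM of the total count without TMM factors. Replicate numbers did not pair libraries across groups (correlations of deviations from -0.0213 to 0.106). No 2 libraries of the same group were duplicates (chi-square per degree of freedom 2.48 to 59.3 within groups and 233 to 244 for DMSO across the naming sets). Libraries of different groups were not checked for duplicates. The first principal component held 35.6% of the variance in MDA-MB-231 and 65.7% in 4T1. TMM factors were 0.766 and 0.784 for 4T1 ENMD-2076 2.5 µM and 0.989 to 1.12 for the other 4T1 libraries.

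A total of 26 gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 104 tests against DMSO and separately over 78 tests between doses and compounds, with camera at an estimated correlation and fry beside it. They covered Aurora kinases and partners, mitosis, DNA replication, p53 targets, T and NK cell chemokines, myeloid chemokines and cytokines, interferon-stimulated genes, MHC class I and II, checkpoint ligands, NK cell receptor ligands, STAT3, NF-kB and ERK targets, cholesterol synthesis, lysosome, integrated stress response, unfolded protein response, epithelial-mesenchymal transition, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, mitochondrially encoded genes, and haematopoietic, fibroblast and endothelial markers. The cell-cycle ID lists of scran 1.30.0 were added after the counts had been seen. They were built from the gene pairs of its cell-cycle classifier, as the first genes of the pairs of 1 phase only. Named genes were Aurka, Aurkb, Ccl5, Cxcl9, Cxcl10, Cxcl11, Cd274, Stat3 and Socs3. To these were added, per compound at its higher dose, the 4 genes with the largest rise and the 4 with the largest fall past the threshold. They had an average log2 CPM of at least 3, a symbol, and both treated libraries on the same side of every DMSO library compared. That average was taken over all 4T1 libraries, so a gene could pass it through groups outside its comparison and be scarcely expressed within it. Up to 3 list members with the smallest adjusted p, and 3 genes per side for each dose or compound difference, completed them. Groups, lists, tests, alternatives and this rule were fixed before the data were examined. Y-linked genes, Hnf4a and the other transcripts of set 2 were chosen after their values were seen. Some genes that the rule names are not reported here.

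Overlaps and correlations that share DMSO libraries were compared with 20 simulated draws without compound effects. The pipeline was tested on simulated data in which 200 genes per comparison were changed: 68 to 80% of shifts of 1 log2 unit were recovered in MDA-MB-231 and 80 to 91% in 4T1, and 90 to 98% of shifts of 2, with 5 to 17 other genes called. The changed genes were balanced up and down and at 1 CPM or more in DMSO. These rates therefore do not cover ENMD-2076 in 4T1, where 7056 and 10816 genes were called and scaling matters more. Alternatives were DESeq2 1.42.0, RLE factors, no filter, a filter of 1 CPM in 2 libraries, leaving out each library, a replicate block, fits of the 2 compared groups alone, 4T1 DMSO pooled without the naming set, and estimated correlations. Total-count scaling, 1 naming set alone, leaving out both libraries of a group that stood apart, thinned counts and removal of mitochondrially encoded genes, Gm26917 and Gm15564 were added later. Splits of the samples into other groups were not counted, because every compound group held 2 libraries. Plots used Python 3.11.15 and matplotlib 3.10.9.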

Results

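RNA was sequenced from human MDA-MB-231 and mouse 4T1 cells, lines derived from triple-negative breast cancer and from a mammary carcinoma of a female mouse, after 24 h with ENMD-2076, TAK901 or the solvent DMSO. Both compounds are known as inhibitors of Aurora kinases, the enzymes that drive centrosome maturation and chromosome segregation. MDA-MB-231 cells received 2.5 or 5 µM ENMD-2076 or 1 or 2 µM TAK901. Cells labelled 4T1 received 1.25 or 2.5 µM ENMD-2076 or 1 or 2 µM TAK901. Each group held 2 libraries, except 4T1 DMSO with 4, for 22 libraries in all. Gene counts summed to 13.4 to 24.0 M reads per MDA-MB-231 library. In 4T1 they summed to 14.4 to 30.9 M reads, apart from TAK901 at 2 µM with 6.00 and 3.75 M reads. The question in each line was which genes, and which cell-cycle and immune gene groups, differed from DMSO at each dose. The labels do not say that replicates were separate cultures, so every p below measures only the spread between these libraries, which may be technical.

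The libraries labelled 4T1 fell into 2 naming sets that differed before any compound was considered. Set 1 held DMSO 1 and 2 and all ENMD-2076 libraries, and set 2 held DMSO 3 and 4 and all TAK901 libraries. Reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were 0 in all 6 set 1 libraries and summed to 1004 to 7021 in each of the 6 set 2 libraries. As 4T1 derives from a female mouse, these reads argue against 4T1 cells as the only source of RNA in set 2. Hnf4a, a transcription factor of gut and liver epithelium, was at 0 CPM (counts scaled to library size) in set 1 DMSO and at 210 ± 5.96 CPM in set 2 DMSO (mean ± SD, n = 2). The transcription factors Cdx2 and Pdx1 stood at 37.7 and 38.2 CPM in set 2 DMSO, and the cell-cycle inhibitors Cdkn2a and Cdkn2b at 84.2 ± 4.98 and 33.9 CPM. Xist was at or under 0.289 CPM in every library. Between the DMSO libraries of the 2 sets 10341 of 15375 tested genes differed, 5633 higher and 4708 lower in set 2. Each 4T1 compound was compared with the DMSO libraries of its own set, within 1 fit that held the naming set as a term. That choice rested on titles and file names and was fixed before the data were examined. Mitochondrially encoded genes took 3.92 and 4.13% of reads in set 1 DMSO, 6.21 and 7.09% with 1.25 µM ENMD-2076, and 8.83 and 8.72% with 2.5 µM. They took 1.94 and 2.04% in set 2 DMSO and 2.64 to 2.98% with TAK901. Gm26917, a transcript with ribosomal RNA-like sequence, stood at 36.5 and 29.9 CPM in set 1 DMSO, 50.6 and 41.7 with 1.25 µM ENMD-2076, and 2185 and 2004 with 2.5 µM.

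**Figure D1:**
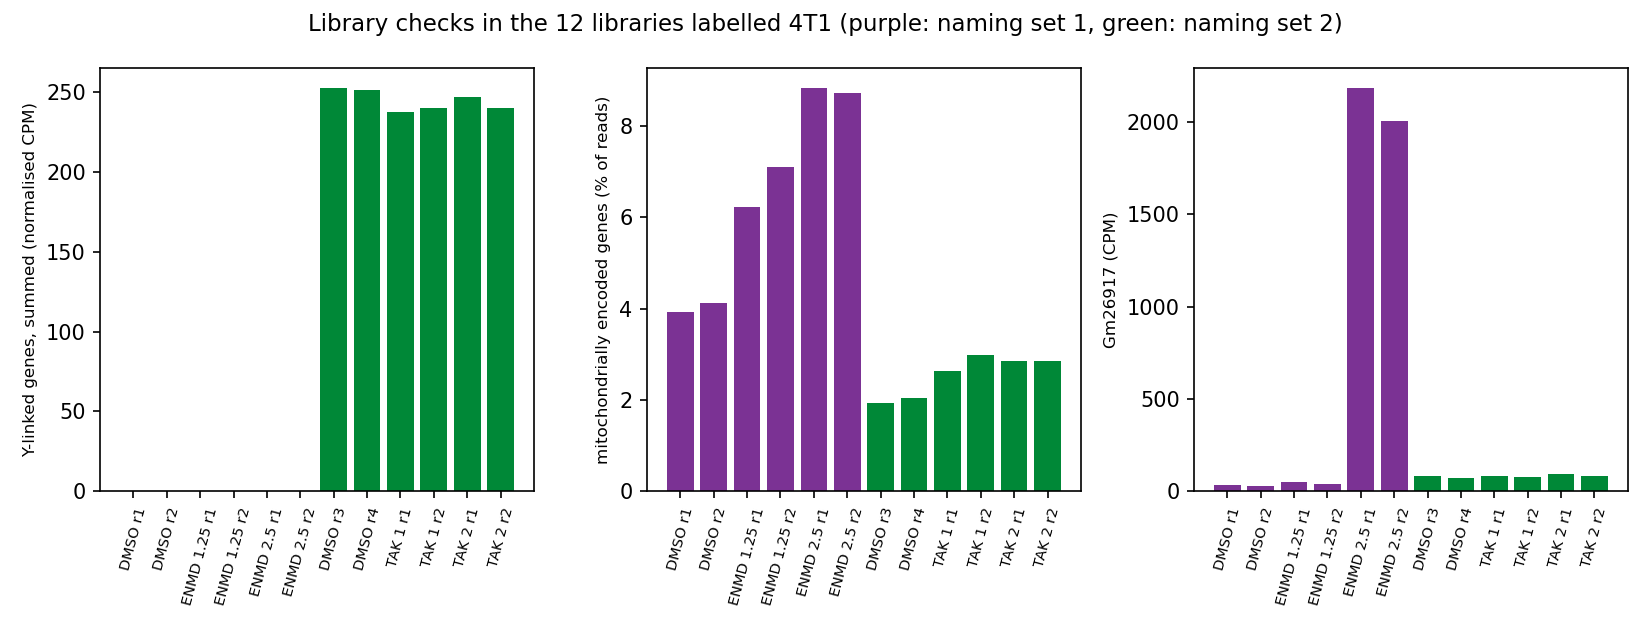
Bars give, for each of the 12 libraries labelled 4T1, the summed normalised CPM of 4 Y-linked genes, the percent of reads in mitochondrially encoded genes and the CPM of Gm26917 (purple, naming set 1; green, naming set 2). Y-linked reads are at 0 in set 1, and Gm26917 is at 2185 and 2004 CPM in the ENMD-2076 2.5 µM libraries.

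In MDA-MB-231 cells ENMD-2076 changed 90 of 14826 tested genes at 2.5 µM, 77 higher and 13 lower, and 725 at 5 µM, 400 higher and 325 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). At 5 µM 137 genes rose and 13 fell by more than 2-fold. These genes are given by ID because no human name table was used here. ENSG00000162804.9 rose from 3.01 ± 0.324 CPM in DMSO to 13.7 ± 2.46 CPM at 5 µM, a log2 fold change of 2.18 (SE 0.23, adjusted p = 2.9e-04). Its log2 fold change at 2.5 µM was 1.21 (adjusted p = 0.0366). ENSG00000265150.1 fell from 131 ± 24.2 to 42.7 ± 10.1 CPM at 5 µM (log2 fold change -1.61, SE 0.21, adjusted p = 9.7e-04). Of cell-cycle gene IDs drawn from the scran classifier, 3 of 43 G2/M genes rose and 5 fell at 5 µM, and 4 of 29 S-phase genes fell. Neither these lists nor the G1 list of 22 passed camera at either dose or with TAK901 (adjusted p from 0.234 to 0.874). That does not show an unchanged cell cycle. In 4T1 at 1.25 µM ENMD-2076 the scran S-phase list did not pass either (median -0.05, camera adjusted p = 0.317), where 30 of 30 DNA replication genes fell. Without both TAK901 2 µM libraries, whose replicates differed most, 953 genes changed at 2.5 µM, 468 higher and 485 lower, and 2460 at 5 µM, 1112 higher and 1348 lower. Fits of the 2 groups alone gave 401 higher and 412 lower at 2.5 µM, and 1153 higher and 1350 lower at 5 µM.

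For the 2.5 µM count, leaving out 1 library gave 966 without TAK901 2 µM replicate 1 and 948 without its replicate 2. The count was 14 without DMSO replicate 1, 14 without DMSO replicate 2, 14 without ENMD-2076 2.5 µM replicate 1 and 11 without its replicate 2. It was 31 and 30 without ENMD-2076 5 µM replicate 1 or 2, and 46 and 42 without TAK901 1 µM replicate 1 or 2. For the 5 µM count it gave 2418 and 2420 without TAK901 2 µM replicate 1 or 2, 79 and 151 without DMSO replicate 1 or 2, and 82 and 67 without ENMD-2076 5 µM replicate 1 or 2. It was 412 and 418 without ENMD-2076 2.5 µM replicate 1 or 2.

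TAK901 changed 2065 MDA-MB-231 genes at 1 µM, 958 higher and 1107 lower, and 4623 at 2 µM, 2252 higher and 2371 lower. At 2 µM 913 rose and 590 fell by more than 2-fold. ENSG00000004799.7 rose from 1.05 ± 0.745 CPM in DMSO to 23 ± 6.64 CPM at 2 µM (log2 fold change 4.40, SE 0.37, adjusted p = 2.2e-06), with 3.20 at 1 µM and 2.08 with 5 µM ENMD-2076. ENSG00000189057.6 fell from 78.7 to 12.7 CPM at 2 µM (log2 fold change -2.63, SE 0.18, adjusted p = 5.6e-07). ENSG00000162804.9 also rose with TAK901, by 2.32 at 1 µM and 2.50 at 2 µM on the log2 scale. Of the scran lists at 2 µM, 8 G2/M genes rose and 12 fell, and 3 S-phase genes rose and 8 fell. The 1 µM count was 812 and 802 without DMSO replicate 1 or 2, 776 and 739 without TAK901 1 µM replicate 1 or 2, and 3975 and 3995 without TAK901 2 µM replicate 1 or 2. The 2 µM count was 2893 and 2843 without DMSO replicate 1 or 2.

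**Figure D2:**
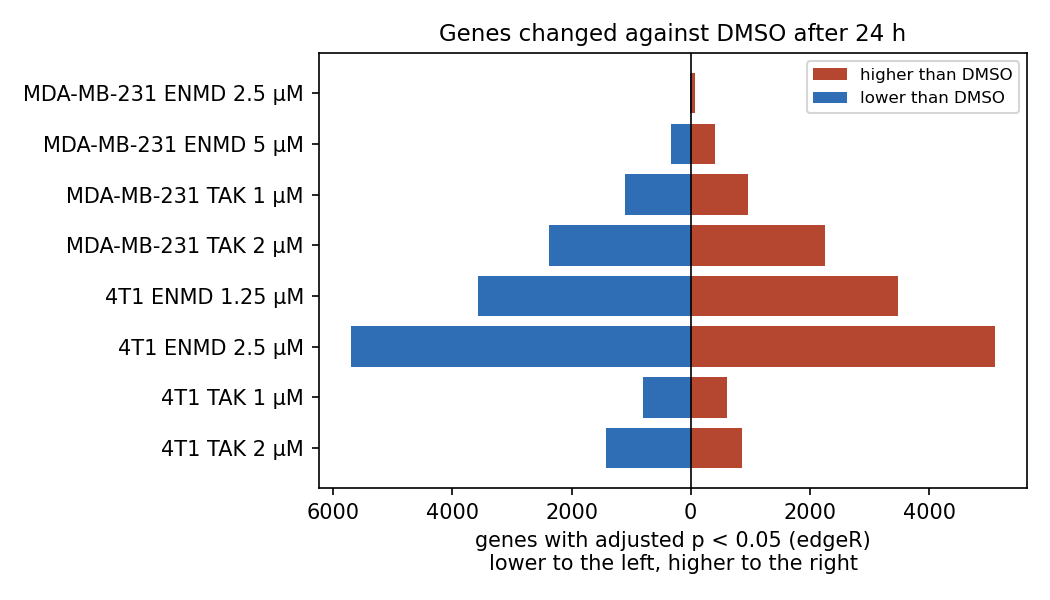
Bars give the number of genes with an adjusted p under 0.05 (edgeR) against DMSO for each compound and dose in both lines, higher to the right and lower to the left of 0. The counts run from 90 with 2.5 µM ENMD-2076 in MDA-MB-231 to 10816 with 2.5 µM in 4T1.

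Between doses in MDA-MB-231, 2 genes differed for ENMD-2076, 1 higher and 1 lower at 5 µM (edgeR, with 804 at an unadjusted p under 0.05, and 7 with DESeq2), and 555 for TAK901, 161 higher and 394 lower at 2 µM (675 and 694 without a filter). The pair, named after the values were seen, was ENSG00000227234.1 (higher at 5 µM, adjusted p = 1.3e-05) and ENSG00000164283.8 (log2 difference -0.78, SE 0.11, adjusted p = 0.0406). With only the 2 groups fitted, the counts between doses were 335 higher and 372 lower for ENMD-2076 and 0 for TAK901. The ENMD-2076 count was 64 and 62 without TAK901 2 µM replicate 1 or 2 and 1 without any other single library. The TAK901 dose count was 22 without TAK901 1 µM replicate 2 and 64 without its replicate 1, and 981 and 3581 without TAK901 2 µM replicate 1 or 2, the latter as 1663 higher and 1918 lower. It was 195 and 194 without ENMD-2076 5 µM replicate 1 or 2, 198 and 224 without 2.5 µM replicate 1 or 2, and 327 and 285 without DMSO replicate 1 or 2. Calls of the 2 doses against the same DMSO libraries went the same way for 87 of 87 genes with ENMD-2076 and 1781 of 1782 with TAK901. Shared DMSO libraries favour equal signs: log2 fold changes of the doses correlated across genes at 0.698 and 0.769, where simulated data without compound effects gave 0.529 and 0.494 (covariances 0.271 and 0.545 against 0.107 and 0.107). Between 5 µM ENMD-2076 and 2 µM TAK901, 608 genes were called against DMSO for both, 289 higher and 303 lower in both and 16 in opposite directions. Independence would give 60.8 and 52.0. The log2 fold changes of the compounds correlated across genes at 0.619, where simulated data with the shared DMSO libraries and no compound effect gave 0.511 on average. Their covariance was 0.374 against 0.107 simulated, and genes are not independent replicates. The compounds were compared directly at these doses, which differ. ENMD-2076 had 1477 genes higher and 1095 lower than TAK901. That count of 2572 was 861 and 883 without ENMD-2076 5 µM replicate 1 or 2 and 4612 without TAK901 2 µM replicate 2. The shared count of 592 in 1 direction was 55 to 1786 over the libraries left out. It was 66 and 55 without ENMD-2076 5 µM replicate 1 or 2, 339 and 345 without 2.5 µM replicate 1 or 2, 59 and 123 without DMSO replicate 1 or 2, and 1786 and 1424 without TAK901 2 µM replicate 1 or 2.

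In the 4T1 libraries labelled ENMD-2076 1.25 µM the genes of cell division fell together. Aurkb, the kinase of the chromosomal passenger complex (ENSMUSG00000020897.6, chromosome 11, 69045647 to 69051664), fell from 54.9 ± 4.39 CPM in DMSO 1 and 2 to 3.20 ± 0.441 CPM, a log2 fold change of -4.06 (SE 0.12, adjusted p = 7.4e-23). Aurka (ENSMUSG00000027496.9, chromosome 2, 172356190 to 172370535) fell from 75 ± 11.9 to 8.70 ± 0.142 CPM (log2 fold change -3.11, SE 0.12, adjusted p = 2.4e-20). All 30 measured mitosis genes fell, with a median log2 fold change of -3.10 (camera adjusted p = 8.4e-51, and 0.0429 with an estimated correlation). They included Cenpe, a kinetochore motor (-3.43), and Cdc20, an activator of the anaphase-promoting complex (-2.90). All 30 DNA replication genes fell as well (median -1.91, camera adjusted p = 4.4e-27, and 0.0429 with an estimated correlation). Among them Mcm3, a subunit of the replicative helicase, fell from 117 ± 1.08 to 24.5 ± 1.46 CPM, and Cdc6, which loads it, by 3.05 on the log2 scale. Of 8 Aurora kinases and partners 7 fell, such as the spindle factor Tpx2 (-3.0), and Ajuba rose (1.35). That list's median was -2.86 (camera adjusted p = 3.4e-09), with an adjusted p = 0.137 with an estimated correlation. Of 21 p53 target genes 8 rose and 7 fell (median 0.09, camera adjusted p = 0.672): Gadd45a rose by 1.25 and Cdkn1a, the inhibitor of cyclin-dependent kinases, fell by 2.74.

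Interferon-stimulated genes rose at 1.25 µM: 19 of 32 rose and 1 fell, or 20 and 1 adjusted over the list alone (median 0.70, camera adjusted p = 6.0e-06, and 0.0429 with an estimated correlation). Parp14 rose by 1.57 and Samd9l by 0.99. Of 20 MHC class I genes 15 rose and 1 fell (median 0.96, camera adjusted p = 1.1e-07, with an adjusted p = 0.137 with an estimated correlation), among them the peptide-loading chaperone Calr (1.11). Cd274, which encodes PD-L1 (ENSMUSG00000016496.7, chromosome 19, 29367455 to 29388095), rose from 1.83 ± 0.248 to 3.16 ± 0.0899 CPM (log2 fold change 0.79, SE 0.30, adjusted p = 0.0317). Ccl5, a chemokine that attracts T cells (ENSMUSG00000035042.2, chromosome 11, 83525778 to 83530518), rose from 1.38 ± 0.873 to 4.44 ± 0.831 CPM (log2 fold change 1.68, SE 0.46, adjusted p = 0.00287). Cxcl10 had at most 25 reads in any library, at 0.0295 CPM in DMSO 1 and 2, 0.540 CPM at 1.25 µM and 0.884 CPM at 2.5 µM (adjusted p = 0.00305 and 3.7e-04). Cxcl11 had at most 12 reads and did not pass, and Cxcl9 had none. The list of T and NK cell attracting chemokines (3 of 5 rose and 1 fell, median 0.78), that of myeloid chemokines and cytokines (5 of 16 rose and 8 fell, median -0.20) and that of MHC class II genes (3 of 5 rose, median 0.74) did not pass camera (adjusted p = 0.423, 0.936 and 0.122). Neither did checkpoint ligands (7 of 12 rose and 3 fell, or 7 and 4 adjusted over the list alone, adjusted p = 0.754) nor NK cell receptor ligands (1 of 5 rose and 2 fell, adjusted p = 0.341).

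Among signalling and metabolic groups at 1.25 µM, 17 of 19 ERK-dependent early genes fell and 1 rose (median -1.75, camera adjusted p = 1.7e-15, with an adjusted p = 0.0786 with an estimated correlation). The ERK phosphatase gene Dusp6 fell from 244 ± 3.44 to 35.3 ± 1.86 CPM. Of 23 integrated stress response genes 21 fell and 1 rose (median -1.63, camera adjusted p = 7.7e-21, and 0.0429 with an estimated correlation), such as Trib3 (-4.47) and the cystine transporter gene Slc7a11 (-3.18). Cholesterol synthesis genes rose, 19 of 23 with 2 lower (median 0.65, camera adjusted p = 3.3e-09, with an adjusted p = 0.154 with an estimated correlation). All 28 ribosomal protein genes fell (median -0.54, camera adjusted p = 1.1e-12) and all 12 mitochondrially encoded genes rose (median 0.75, camera adjusted p = 2.1e-08), with adjusted p = 0.255 and 0.219 with an estimated correlation. Both groups have near-identical copies in the genome, so their levels depend on how reads with several alignments were counted. Hypoxia and glycolysis genes fell, 17 of 23 with 2 higher (median -0.61, camera adjusted p = 4.9e-07, with an adjusted p = 0.255 with an estimated correlation). Nuclear oxidative phosphorylation genes rose, 19 of 27 with 2 lower, or 20 and 2 adjusted over the list alone (median 0.29, camera adjusted p = 0.00221, with an adjusted p = 0.444 with an estimated correlation). Of 20 NF-kB target genes 11 rose and 4 fell (median 0.39, camera adjusted p = 0.0275, with an adjusted p = 0.353 with an estimated correlation), and without DMSO replicate 2 that list did not pass (adjusted p = 0.0523), nor without both ENMD-2076 2.5 µM libraries (0.0696). Of 28 lysosome genes 12 rose and 4 fell, or 13 and 4 adjusted over the list alone (median 0.21, camera adjusted p = 0.0363, with an adjusted p = 0.487 with an estimated correlation). That list did not pass without DMSO replicate 1 (0.125), ENMD-2076 1.25 µM replicate 1 (0.0787) or both 2.5 µM libraries (0.126). Stat3 rose by 0.44 (SE 0.07, adjusted p = 8.0e-06) and Socs3, a feedback inhibitor that it induces, fell by 2.25 (adjusted p = 8.3e-15), while the list of STAT3 targets did not pass camera (5 of 22 rose and 8 fell, adjusted p = 0.172, and 0.0244 without both ENMD-2076 2.5 µM libraries). Chaperones of the unfolded protein response (4 of 17 rose and 5 fell, or 5 and 6 adjusted over the list alone, adjusted p = 0.993) and epithelial-mesenchymal transition genes (9 of 22 rose and 6 fell, adjusted p = 0.0700) did not pass either, though the latter passed without ENMD-2076 1.25 µM replicate 1 (0.0331) or without DMSO replicate 1 (0.0343) or 2 (0.0406) or both ENMD-2076 2.5 µM libraries (0.00640).

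The libraries labelled ENMD-2076 2.5 µM went another way in several of these groups, and they were also the libraries with Gm26917 at 2185 and 2004 CPM. Mcm3 rose to 934 ± 1.72 CPM (log2 fold change 3.0) and Cdc6 from 14.2 ± 0.0690 CPM in DMSO 1 and 2 to 275 ± 6.82 CPM (4.28). Of 30 DNA replication genes 27 rose and 1 fell (median 1.47, camera adjusted p = 6.1e-12, and 0.0429 with an estimated correlation). Aurka stood at 75.7 ± 3.18 CPM (log2 fold change 0.01, SE 0.09, adjusted p = 0.932), but with total-count scaling its log2 fold change was -0.34 (adjusted p = 0.00159). Aurkb fell by 0.60 (SE 0.09, adjusted p = 6.0e-07). Of 30 mitosis genes 24 fell and 1 rose (median -0.80, camera adjusted p = 6.0e-06, with an adjusted p = 0.255 with an estimated correlation), with Cenpe at -2.37 and Cdc20 at -2.02. The Aurora list had 3 higher and 3 lower genes (camera adjusted p = 0.987) and p53 targets 6 higher and 11 lower of 21 (0.391). Cdkn1a fell by 2.17 and Gadd45a fell by 3.59. The scran lists were added after the counts had been seen. Of 34 S-phase genes 11 rose and 15 fell at 1.25 µM (median -0.05, camera adjusted p = 0.317) and 15 rose and 12 fell at 2.5 µM (median -0.02, 0.919). Of 29 G2/M genes 20 fell and 2 rose at 1.25 µM (1.3e-12, with an adjusted p = 0.112 with an estimated correlation), and 21 fell and 6 rose at 2.5 µM (0.0384, with an adjusted p = 0.373 with an estimated correlation). Of 11 G1 genes 6 fell and 2 rose at 1.25 µM (0.0459, with an adjusted p = 0.236 with an estimated correlation), and 7 rose and 4 fell at 2.5 µM (0.165).

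**Figure D3:**
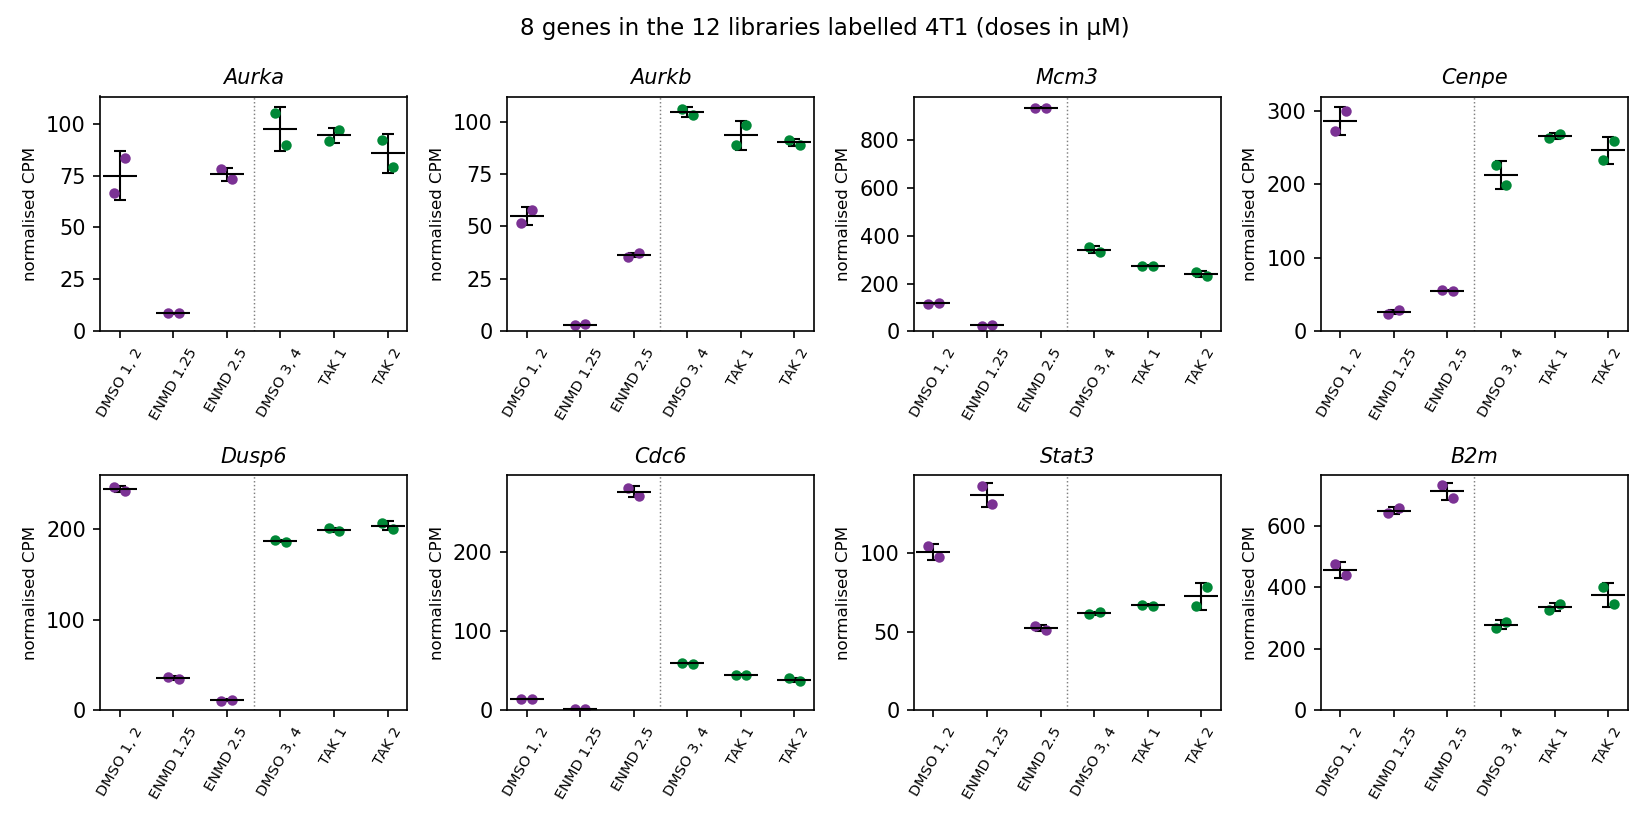
Points give the normalised CPM of Aurka, Aurkb, Mcm3, Cenpe, Dusp6, Cdc6, Stat3 and B2m in each of the 12 libraries labelled 4T1, with the mean and SD of each pair (purple, naming set 1; green, naming set 2). Mcm3 is at 117 CPM in DMSO 1 and 2, 24.5 with 1.25 µM and 934 with 2.5 µM ENMD-2076.

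Immune gene groups at 2.5 µM went down or both ways. Of 32 interferon-stimulated genes 21 fell and 4 rose (median -1.20, camera adjusted p = 0.0294, with an adjusted p = 0.143 with an estimated correlation), with Parp14 at -1.93 and Samd9l at -1.55. That list did not pass without DMSO replicate 1 (adjusted p = 0.0543) or with total-count scaling (0.0565). Of 12 checkpoint ligands 8 fell and 1 rose (median -1.50, camera adjusted p = 0.0184, with an adjusted p = 0.255 with an estimated correlation). Pvr, a ligand of TIGIT, fell by 2.12 and Cd47, the signal against phagocytosis, by 1.94, while Cd274 rose to 4.93 ± 0.346 CPM (log2 fold change 1.43, SE 0.30, adjusted p = 9.4e-05). MHC class I genes went both ways, 7 of 20 higher and 7 lower (camera adjusted p = 0.987): Calr rose by 1.95 and Pdia3 by 1.42, and H2-T23 fell by 3.10. Stat3 fell by 0.94 (SE 0.08, adjusted p = 5.3e-12) and Socs3 by 0.79 (adjusted p = 2.3e-06). Of 22 STAT3 targets 12 fell and 6 rose (median -0.91, camera adjusted p = 0.0396, with an adjusted p = 0.254 with an estimated correlation), with Myc at -2.69 and Cebpb at -3.18. This list passed narrowly, since leaving out either 2.5 µM library, DMSO replicate 3 or 4, or any TAK901 library gave adjusted p = 0.0525 to 0.0639, and the replicate block 0.0790. Ccl5 did not pass at 2.5 µM (log2 fold change -0.18, adjusted p = 0.804), but without 2.5 µM replicate 1 it was -2.35 (adjusted p = 0.0147). NF-kB targets (7 of 20 higher and 12 lower, adjusted p = 0.162), chemokines for T and NK cells (1 of 5 higher and 2 lower, 0.306), myeloid chemokines and cytokines (4 of 16 higher and 7 lower, 0.503), MHC class II (1 of 5 higher and 2 lower, 0.936) and NK cell receptor ligands (3 of 5 lower, 0.453) did not pass camera.

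ERK-dependent early genes also fell at 2.5 µM, 17 of 19 (median -1.79, camera adjusted p = 2.6e-07, with an adjusted p = 0.143 with an estimated correlation), and Dusp6 reached 11 ± 0.764 CPM. Of 23 integrated stress response genes 14 fell and 3 rose (median -0.78, camera adjusted p = 1.4e-04, with an adjusted p = 0.103 with an estimated correlation), with Trib3 at -5.23. Cholesterol synthesis genes rose, 16 of 23 with 4 lower (median 1.06, camera adjusted p = 3.2e-06, with an adjusted p = 0.254 with an estimated correlation). Fdft1, which encodes squalene synthase, had log2 fold changes of 0.99 at 1.25 µM and 3.28 at 2.5 µM. Chaperones of the unfolded protein response rose, 15 of 17 with 2 lower (median 0.98, camera adjusted p = 6.0e-06, with an adjusted p = 0.0875 with an estimated correlation), such as Dnajb11 (2.45). All 27 nuclear oxidative phosphorylation genes rose (median 1.19, camera adjusted p = 4.4e-12, with an adjusted p = 0.178 with an estimated correlation). Of 28 ribosomal protein genes 26 rose (median 0.59, camera adjusted p = 4.3e-07), and all 12 mitochondrially encoded genes rose (median 1.46, camera adjusted p = 2.0e-08), with adjusted p = 0.392 and 0.215 with an estimated correlation. Lysosome genes (11 of 28 higher and 14 lower, adjusted p = 0.400), hypoxia and glycolysis genes (15 of 23 higher and 7 lower, 0.0622, though 0.0357 to 0.0462 under 5 other settings) and epithelial-mesenchymal transition genes (7 of 22 higher and 11 lower, 0.341) did not pass.

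The genes with the largest rise at 2.5 µM had few or no reads in DMSO 1 and 2. Taf9b, a subunit of transcription factor complexes (ENSMUSG00000047242.8, chromosome X, 106206883 to 106221158), went from 0.0589 to 61.4 ± 2.49 CPM (adjusted p = 3.5e-21), and the cytokine gene Il17f from 0.0565 to 55.2 ± 2.13 CPM (4.2e-19). Colec11, a soluble lectin gene, went from 0.118 to 71.1 ± 1.46 CPM (9.6e-20). Hhex, a transcription factor gene, had no reads in DMSO 1 and 2 and 3.99 ± 0.109 CPM at 2.5 µM, at least 23.6-fold higher with a floor of 3 reads per library. In the set 2 DMSO libraries it stood at 35.4 ± 0.307 CPM. Tcp11l2 (ENSMUSG00000020034.7, chromosome 10, 84576626 to 84614359) fell from 35.6 ± 1.41 to 0.215 ± 0.0535 CPM (adjusted p = 5.2e-21), a level near the floor of 3 reads. Add2, Myo7a and Ppp1r1b had no reads at 2.5 µM and were at least 23.5-fold, 3.25-fold and 2.73-fold lower than in DMSO 1 and 2. The DMSO levels of Myo7a and Ppp1r1b were thus only a few times that floor.

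At 1.25 µM 7056 of 15375 genes changed, 3482 higher and 3574 lower, and at 2.5 µM 10816, 5111 higher and 5705 lower. Changes over 2-fold numbered 1000 higher and 1222 lower at 1.25 µM, and 2811 and 3375 at 2.5 µM. With total-count scaling the 2.5 µM split was 3760 higher and 7247 lower, and the median gene lay at -0.37 on the log2 scale instead of near 0. Replicate blocking gave 6886 and 10735 genes. With all 4 DMSO libraries pooled across the naming sets, the 1.25 µM count was 3101.

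Tested directly, 11264 genes differed between the libraries labelled 2.5 and 1.25 µM, 5448 higher and 5816 lower at 2.5 µM (4177 and 7343 with total-count scaling). DNA replication genes were higher at 2.5 µM in 30 of 30 cases (median difference 3.24, camera adjusted p = 1.0e-21, with an adjusted p = 0.147 with an estimated correlation), and so were 30 of 30 mitosis genes (2.30, 6.2e-18, with an adjusted p = 0.213 with an estimated correlation). Interferon-stimulated genes were lower in 26 of 32 and higher in 2 (median -1.81, camera adjusted p = 4.1e-05, with an adjusted p = 0.135 with an estimated correlation). All 28 ribosomal protein genes were higher (median 1.10, camera adjusted p = 3.9e-13, with an adjusted p = 0.337 with an estimated correlation). The largest fitted differences involved groups with few or no reads, so levels are given without folds. Upward they were Colec11 (0.0966 CPM at 1.25 µM and 71.1 at 2.5 µM) and Il17f and Trim71, which had no reads at 1.25 µM and stood at 55.2 and 1.91 CPM at 2.5 µM. Downward they were Klhdc7a (46.5 and 0.0316 CPM), Mgat3 (26.4 and 0.0316 CPM) and Myo7a, at 2.93 CPM at 1.25 µM and without reads at 2.5 µM. Of 5661 genes called against DMSO at both doses, 2930 went the same way (51.8%), 1217 higher and 1713 lower in both, and 1492 rose at 1.25 µM but fell at 2.5 µM. Independence would give 1157 genes higher and 1326 lower in both. Across genes the log2 fold changes of the doses correlated at 0.215, where simulations with shared DMSO libraries and no compound effect gave 0.489 with a smaller covariance (0.185 against 0.550). The same libraries also differed in Gm26917 and in their share of mitochondrial reads. Their column headers read 4T1_1_10uM for the pair labelled 1.25 µM and 4T1_2_10uM for that labelled 2.5 µM, so the difference in dose rests on the labels.

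**Figure D4:**
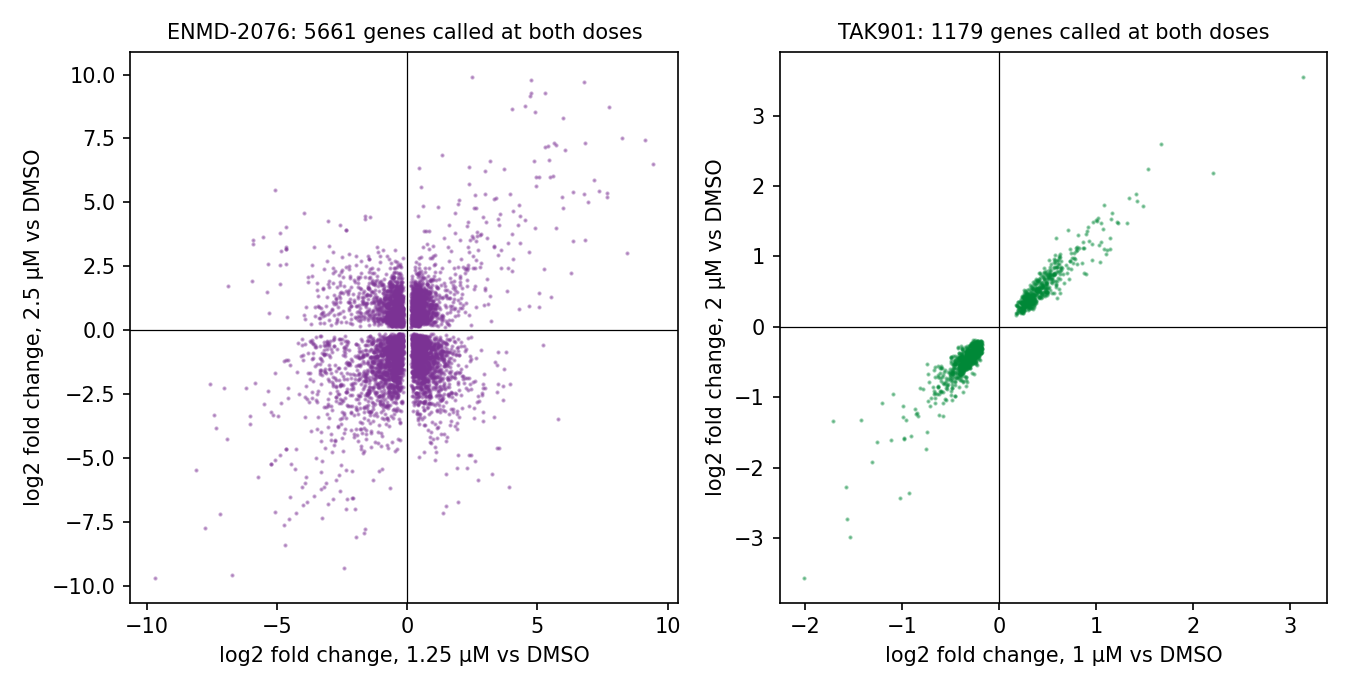
Each point is a gene called against DMSO at both doses in 4T1, with the log2 fold change at the lower dose on the horizontal axis and at the higher dose on the vertical axis, for ENMD-2076 and TAK901. For ENMD-2076 51.8% of 5661 genes lie in the quadrants of equal sign, and for TAK901 all 1179 do.

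The TAK901 libraries labelled 4T1 were compared with DMSO 3 and 4, and all 6 of these carried the Y-linked reads. Which cells the changes below belong to was therefore not established. DNA replication genes fell at both doses, 17 of 30 at 1 µM and 26 at 2 µM, or 27 and 28 adjusted over the list alone. Their medians were -0.28 and -0.48 (camera adjusted p = 1.1e-18 and 1.4e-23, and 0.0359 and 0.0106 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell by 0.68 at 2 µM (SE 0.07, adjusted p = 9.6e-08), Tk1 by 0.63, and Mcm3 from 341 ± 13.8 CPM in DMSO 3 and 4 to 274 ± 1.70 at 1 µM and 240 ± 11.3 at 2 µM. Mitosis genes did not pass as a list: at 2 µM 5 of 30 fell, or 7 with 1 higher adjusted over the list alone (median -0.02, camera adjusted p = 0.325), among them Top2a (-0.31). At 1 µM 1 rose (0.298). Of the scran lists G1 passed, with 4 of 11 genes lower at 1 µM and 6 at 2 µM (camera adjusted p = 9.8e-04 and 6.6e-04, with an adjusted p = 0.118 with an estimated correlation at either dose), and those of S phase (0.261 at either dose) and G2/M (0.778 and 0.314) did not. Aurka (-0.17, SE 0.10, adjusted p = 0.286) and Aurkb (-0.21, adjusted p = 0.102) did not pass at 2 µM, nor did any of the 8 genes of their list at either dose (camera adjusted p = 0.492 at 1 µM and 0.280 at 2 µM). p53 target genes rose, 6 of 21 at 1 µM and 7 with 1 lower at 2 µM, or 8 and 8 with 1 lower adjusted over the list alone (medians 0.16 and 0.13, camera adjusted p = 6.7e-05 and 3.0e-04). The call at 1 µM held with an estimated correlation (adjusted p = 0.0474), and at 2 µM it did not (adjusted p = 0.0875 with an estimated correlation). Trp53inp1 rose by 0.61 and Btg2 by 0.86 at 2 µM.

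Some MHC class I genes rose at both doses of TAK901, and at 2 µM some interferon-stimulated genes did. Of 20 MHC class I genes 5 rose at 1 µM and 9 at 2 µM, or 10 with 1 lower at 2 µM adjusted over the list alone (medians 0.23 and 0.38, camera adjusted p = 8.5e-05 and 9.6e-07, with adjusted p = 0.215 and 0.170 with an estimated correlation). B2m, the light chain of MHC class I, rose from 278 ± 14.4 CPM in DMSO 3 and 4 to 336 ± 11.8 at 1 µM and 374 ± 38.9 at 2 µM, and Tapbp rose by 0.53 at 2 µM. H2-D1 rose by 0.41, though H2 genes resemble each other closely and their reads may be shared. Of 32 interferon-stimulated genes 8 rose and 2 fell at 2 µM (median 0.25, camera adjusted p = 0.00488, with an adjusted p = 0.0975 with an estimated correlation), and 5 rose and 1 fell at 1 µM, or 7 and 1 adjusted over the list alone (0.162). Gbp2, an interferon-induced GTPase gene, rose from 5.64 ± 0.586 to 16.8 ± 1.95 CPM at 2 µM (log2 fold change 1.55, SE 0.19, adjusted p = 6.7e-07). Of 20 NF-kB targets 8 rose and 1 fell at 2 µM, or 10 and 1 adjusted over the list alone (median 0.25, camera adjusted p = 2.7e-05, with an adjusted p = 0.170 with an estimated correlation), Nfkbia by 0.57 and Ptgs2 by 0.41. At 1 µM 5 rose and 1 fell (camera adjusted p = 1.1e-04, with an adjusted p = 0.195 with an estimated correlation). Single chemokine and cytokine genes rose at 2 µM, Cxcl16 by 0.79, Cxcl3 by 0.78 and Csf1 by 0.59. The lists of T and NK cell chemokines (1 of 5 rose, adjusted p = 0.170), myeloid chemokines and cytokines (3 of 16 rose, or 4 with 1 lower adjusted over the list alone, 0.0706), MHC class II (1 of 5 rose, 0.0706), checkpoint ligands (2 of 12 rose and 2 fell, 0.421) and STAT3 targets (4 of 22 rose and 5 fell, or 8 and 5 adjusted over the list alone, 0.162) did not pass at 2 µM. The myeloid list passed within set 2 alone (0.00208), with the 2 groups alone (0.0126), without both ENMD-2076 2.5 µM libraries (0.0138), with the stricter filter (0.0410) and without DMSO replicate 1 (0.0491) or ENMD-2076 1.25 µM replicate 2 (0.0477), and the MHC class II list without DMSO replicate 3 (0.0433), TAK901 1 µM replicate 2 (0.0444) or TAK901 2 µM replicate 2 (0.0474). None of 5 NK cell receptor ligands passed. Cd274 (-0.13, adjusted p = 0.870), Ccl5 (-0.15, 0.933), Cxcl10 (-0.69, 0.691) and Stat3 (0.22, SE 0.09, 0.102) did not pass at 2 µM, although Stat3 passed within set 2 alone (0.0262) and without TAK901 2 µM replicate 1 (log2 fold change 0.35, adjusted p = 0.04999). Socs3 fell by 0.40 (SE 0.13, adjusted p = 0.0264), a call lost with DESeq2 (0.0606), total-count scaling (0.0637) and thinned counts (0.102). It was also lost without DMSO replicate 3 (log2 fold change -0.32), DMSO replicate 4 (-0.47), TAK901 2 µM replicate 1 (-0.31) or replicate 2 (-0.49).

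**Figure D5:**
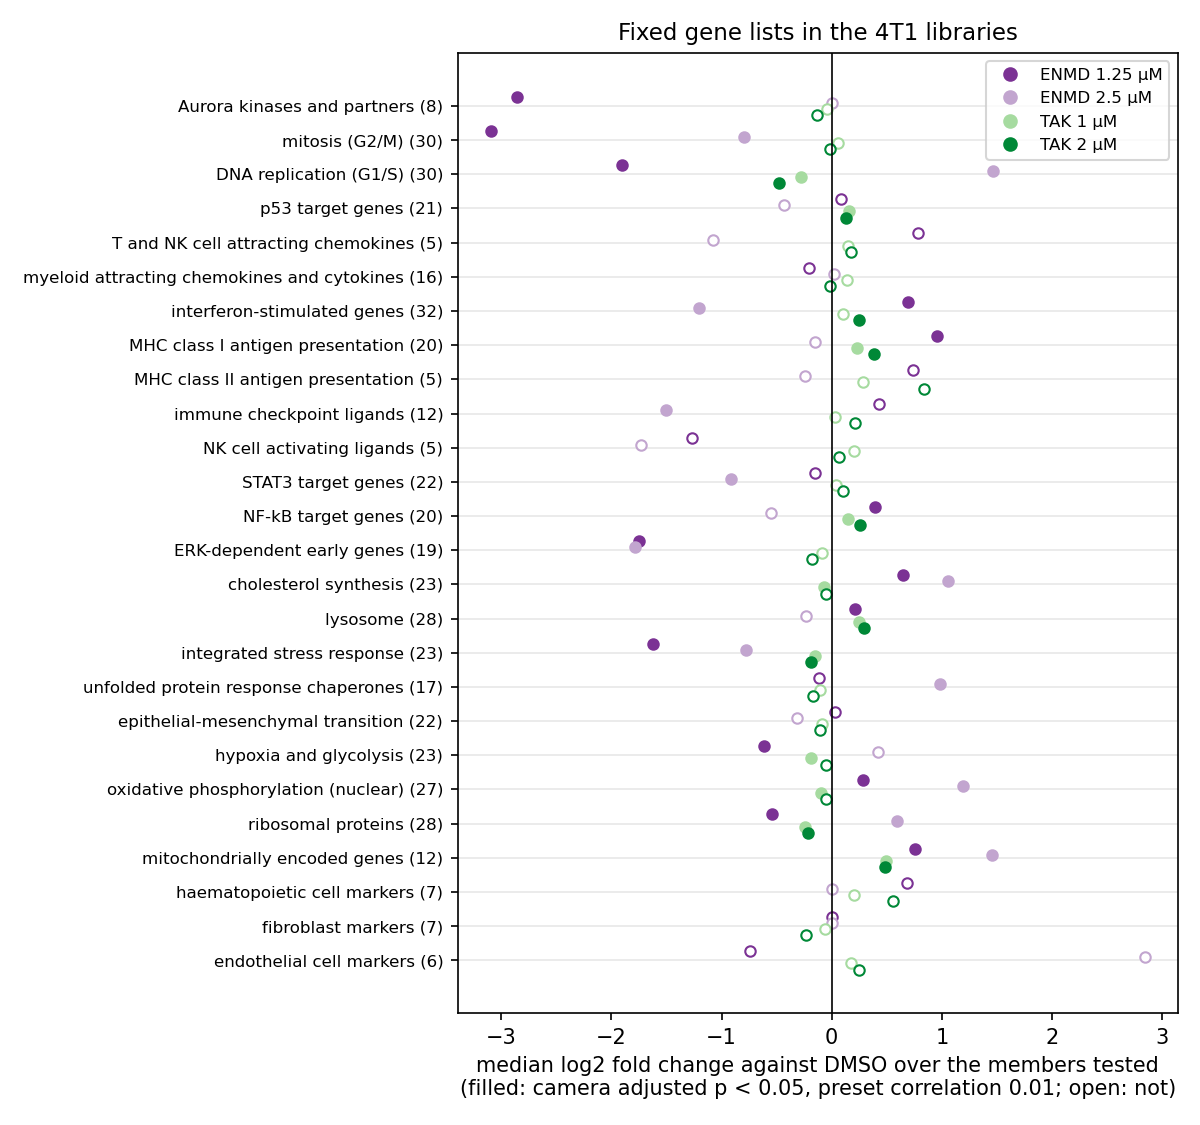
Points give the median log2 fold change against DMSO over the tested members of each of 26 fixed gene lists in the 4T1 libraries for both compounds and doses (filled, camera adjusted p under 0.05 with a preset correlation of 0.01; open, not). DNA replication lies at -1.91 and 1.47 with 1.25 and 2.5 µM ENMD-2076 and at -0.28 and -0.48 with 1 and 2 µM TAK901.

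Lysosome genes rose with TAK901, 16 of 28 with 1 lower at each dose, or 19 and 18 with 1 lower adjusted over the list alone (medians 0.25 and 0.30, camera adjusted p = 3.4e-13 and 1.8e-14, with an adjusted p = 0.103 with an estimated correlation at either dose). Ctsa, a lysosomal carboxypeptidase gene, rose by 0.51 and 0.68, and Gpnmb by 0.52 and 0.73. Integrated stress response genes fell, 6 of 23 with 2 higher at 1 µM and 8 with 3 higher at 2 µM, or 12 with 2 higher and 12 with 4 higher adjusted over the list alone (camera adjusted p = 0.00143 and 0.0158, with adjusted p = 0.0975 and 0.137 with an estimated correlation). The call at 2 µM was lost without TAK901 2 µM replicate 2 (0.0609). The serine synthesis genes Psat1 and Phgdh fell by 0.65 and 0.58 at 2 µM and Asns by 0.60. Ribosomal protein genes fell, 18 and 17 of 28, or 20 and 19 adjusted over the list alone (medians -0.24 and -0.22, camera adjusted p = 2.3e-16 and 1.1e-09, with adjusted p = 0.215 and 0.305 with an estimated correlation). Mitochondrially encoded genes rose, 8 of 12 at each dose, or 9 and 9 adjusted over the list alone (medians 0.49 and 0.48, camera adjusted p = 2.1e-12 and 5.4e-09, with adjusted p = 0.154 and 0.215 with an estimated correlation). Levels of both groups depend on how reads with several alignments were counted. In set 2 DMSO mt-Co2, mt-Atp8, mt-Atp6, mt-Co3 and mt-Nd3 stood at only 0.12 to 29.2 CPM, against 495 to 5689 CPM in set 1 DMSO. Hypoxia and glycolysis genes fell at 1 µM, 9 of 23, or 14 adjusted over the list alone (camera adjusted p = 4.6e-07, with an adjusted p = 0.255 with an estimated correlation), and at 2 µM 6 fell and 2 rose (0.341), passing without DMSO replicate 4 (0.0153). Nuclear oxidative phosphorylation genes passed at 1 µM with 1 of 27 lower (median -0.10, camera adjusted p = 0.00208, with an adjusted p = 0.444 with an estimated correlation), and at 2 µM 2 were lower (0.290), passing without TAK901 2 µM replicate 1 (0.00769). Cholesterol synthesis passed at 1 µM with 1 of 23 lower (median -0.07, camera adjusted p = 0.0280, with an adjusted p = 0.476 with an estimated correlation) but not without DMSO replicate 3 (0.0891), and at 2 µM 2 were lower (0.415). ERK-dependent early genes (5 of 19 lower at 2 µM, or 7 with 1 higher adjusted over the list alone, 0.162) and epithelial-mesenchymal transition genes (4 of 22 higher and 5 lower at 2 µM, 0.936) did not pass. Unfolded protein response chaperones did not pass at 2 µM (2 of 17 higher and 4 lower, 0.0877), but did without ENMD-2076 1.25 µM replicate 1 (0.0472) or TAK901 2 µM replicate 1 (0.0425).

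Single genes with large TAK901 changes at 2 µM included Ltf, which encodes lactoferrin (ENSMUSG00000032496.3, chromosome 9, 111019271 to 111042767), and Mmp10, a matrix metalloproteinase gene (ENSMUSG00000047562.2, chromosome 9, 7502352 to 7510240). Ltf rose from 6.64 ± 0.234 to 40.3 ± 6.47 CPM (log2 fold change 2.59, SE 0.20, adjusted p = 1.5e-10) and Mmp10 fell from 2.25 to 0.270 CPM (adjusted p = 5.0e-04), the latter under the floor of 3 reads of both libraries. Slc44a3 rose by 1.73 and Dynap, Sh2d5 and Prl2c2 fell by 2.44, 1.73 and 1.64. Prl2c2 belongs to a family of near-identical genes, so its reads cannot be assigned to it with certainty. Thbs1, which encodes a matrix glycoprotein, rose by 1.10. Colec11 rose from 0.106 to 1.04 CPM (adjusted p = 0.00781). Both Colec11 and Mmp10 met the rule's average level only through 4T1 libraries outside this comparison. The Colec11 call was lost with DESeq2 (adjusted p = 0.0862) and with thinned counts (0.0864). It was also lost without DMSO replicate 4 (log2 fold change 2.34) or TAK901 2 µM replicate 1 (2.76). At 1 µM these genes went the same way, with Ltf at 1.67, Mmp10 at -1.54 and Thbs1 at 0.80.

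TAK901 changed 1406 genes of the 4T1 libraries at 1 µM, 611 higher and 795 lower, and 2292 at 2 µM, 865 higher and 1427 lower. With total-count scaling these splits were 746 and 640, and 1172 and 1008. The 1 µM count was 454 and 544 without DMSO replicate 3 or 4, and 551 and 376 without TAK901 1 µM replicate 1 or 2. The 2 µM count was 1306 and 1274 without DMSO replicate 3 or 4, and 1245 and 1333 without TAK901 2 µM replicate 1 or 2. Of 1179 genes called at both doses all went the same way, 479 higher and 700 lower, against 34.4 and 73.8 under independence. Their log2 fold changes correlated across genes at 0.465, against 0.283 in simulations with shared DMSO libraries (covariance 0.157 against 0.0617). Between the doses 11 genes differed, 7 higher and 4 lower at 2 µM (22 and 34 with DESeq2, 20 and 61 without a filter), among them Rsph3a (1.03), Selenbp1 (0.94), Ltf (0.92), Nptx1 (-0.76) and Cad (-0.36). Each of these 5 lost its call when a TAK901 library was left out. Ltf also lost it with the replicate block (0.0790) and without DMSO replicate 3 (0.0802) or 4 (0.0801), and Cad without DMSO replicate 3 (0.0646) or 4 (0.0653). The count was 2 and 1 without TAK901 1 µM replicate 1 or 2, 1 and 17 without TAK901 2 µM replicate 1 or 2, and 20, 34 and 32 without ENMD-2076 2.5 µM replicate 2 or 1.25 µM replicate 1 or 2. DNA replication genes were lower at 2 µM as a list (median -0.20, camera adjusted p = 9.2e-14, and 0.0354 with an estimated correlation), although none of the 30 passed singly and 11 were lower adjusted over the list alone.

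The compounds were set side by side at 2.5 µM ENMD-2076 and 2 µM TAK901, doses that differ, each against the DMSO libraries of its own naming set. The TAK901 arm carried the Y-linked reads and Hnf4a and the ENMD-2076 arm did not, so compound cannot be separated from naming set in these values. Of 1920 genes called for both, 599 went the same way (31.2%), 182 higher and 417 lower, where independence would give 287.5 and 529.5, and 1321 opposite ways. The shared count was 336 and 320 without DMSO replicate 3 or 4 and 293 without TAK901 2 µM replicate 1. Across genes the correlation was -0.0922 against 0.00503 simulated, and the covariance -0.141 against 0.00201. With 1.25 µM ENMD-2076, 1288 of 1563 genes called for both went the same way (82.4%). DNA replication genes were higher with 2.5 µM ENMD-2076 than with 2 µM TAK901 in 29 of 30 cases (median 2.02, adjusted p = 0.0172 with an estimated correlation), and ERK-dependent early genes were lower in 16 of 19 and higher in 1 (camera adjusted p = 7.0e-06, with an adjusted p = 0.214 with an estimated correlation). In all 9384 genes differed between these arms, 4471 higher and 4913 lower with ENMD-2076, or 3119 and 6486 with total-count scaling, a contrast that crosses the naming sets. Of the 104 list tests against DMSO 46 passed camera with the preset correlation, and 8 of them also passed with an estimated correlation. The test fry, which asks whether a list's own genes move 1 way and does not compare them with other genes, passed 75.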

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

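The tests of the doses of ENMD-2076 in this part were all chosen after the result was seen. In the libraries labelled 4T1, 3 gene lists passed in opposite directions at 1.25 and 2.5 µM and differed between the doses when tested directly, by camera at the preset correlation. The median log2 difference, 2.5 minus 1.25 µM, was 3.24 for DNA replication, -1.81 for interferon-stimulated genes and 1.10 for ribosomal proteins, with adjusted p = 0.147, 0.135 and 0.337 with an estimated correlation, where none of these differences passed and only DNA replication passed at both doses against DMSO. Mitochondrial and ribosomal RNA-like transcripts (Gm26917, Gm15564 and Gm42418) took 9.57 and 9.43% of reads at 2.5 µM and 6.30 and 7.15% at 1.25 µM. That change in share gives all other genes 1 common log2 shift of -0.0436 (from -0.0512 to -0.0359 over pairs of libraries). The 11264 genes called between the doses differed by a median of 1.30 in size. Shares this small can give no large shift, and a common shift cannot move lists in opposite directions. The comparison could not have come out otherwise, and shows only that reads taken up by these transcripts are too few to give these differences. A change in the RNA that goes along with that share was not tested. Gene length bias is argued against, since transcript length and the change between the doses correlated across 15200 genes at a Spearman rho of only -0.0976. A treatment other than the label in 1 of the pairs cannot be told apart from an effect of dose. Of the genes called at both doses 51.8% moved the same way. Each dose came as 1 pair of libraries without an outside reference for ENMD-2076. The column headers, 4T1_1_10uM and 4T1_2_10uM, name neither the labelled doses nor a compound. Of genes also called with 2 µM TAK901, 1288 of 1563 moved its way at 1.25 µM (82.4%) and 599 of 1920 at 2.5 µM (31.2%). TAK901 shares no DMSO library with these pairs but is another compound in the other naming set. These values set the 2.5 µM pair apart without giving the cause. The other dose pairs gave 1179 of 1179 genes for TAK901 in 4T1 and 87 of 87 and 1781 of 1782 in MDA-MB-231. They share their DMSO libraries, which favours equal signs, and do not decide between dose and another treatment. Whether the pair labelled 2.5 µM held the same cells as the rest of set 1 was not tested. The biological explanation that the design names, a response that turns between these doses, stays open and untested.

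In a summary line outside the gene counts, 40.1% of the records of TAK901 1 µM replicate 1 in 4T1 were not aligned, above the 26.7 and 20% of DMSO 3 and 4.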

How the results depend on the processing

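Total-count scaling, 1 naming set alone, both libraries of a group left out, thinned counts and removal of mitochondrial genes, Gm26917 and Gm15564 were chosen after seeing the data. All 14 counts of genes stayed within 1.5 times under RLE factors, the stricter filter and the replicate block, and so did the 3 tried without mitochondrial genes, Gm26917 and Gm15564, where Gm42418 (4906 and 4863 CPM at ENMD-2076 2.5 µM) was kept. For named genes, 172 kept their side of the threshold, and their direction where called, under DESeq2 and 5 lost a call. With the replicate block 181 did so and 2 lost a call. A change of sign between 2 values that both missed the threshold was not counted. With pooled DMSO only 98 named genes kept their side, 73 lost a call and 12 turned sign, and with thinned counts 69 kept it and 11 lost a call. Of the list tests 66 kept their side with estimated correlations and 38 lost their call, which left 8 passing, and with pooled DMSO 15 lost it and 5 gained it. Hypoxia and glycolysis at ENMD-2076 2.5 µM passed with RLE factors (0.0440), no filter (0.0412), the stricter filter (0.0414), 1 naming set (0.0357) and without mitochondrial genes, Gm26917 and Gm15564 (0.0462). Myeloid chemokines at TAK901 1 µM passed within set 2 (0.0235) and with the 2 groups alone (0.0299), where cholesterol synthesis lost its call (0.0530 and 0.0512), as it did thinned (0.0669) and with total-count scaling (0.0514). The stricter filter ended the calls of lysosome at 1.25 µM (0.0602) and interferon-stimulated genes at 2.5 µM (0.0525) and added epithelial-mesenchymal transition at 1.25 µM (0.0367), and the 2 groups alone ended STAT3 targets at 2.5 µM (0.103). Without a filter MHC class II at 1.25 µM (0.0433), unfolded protein response at TAK901 1 and 2 µM (0.0142 and 0.00624) and oxidative phosphorylation at 2 µM (0.0423) passed too. Beyond these, MDA-MB-231 counts are given for ENMD-2076 2.5 µM, 5 µM and 5 against 2.5 µM, TAK901 1 µM, 2 µM and 2 against 1 µM. DESeq2 gave 232 for the first, 7 for the third and 1008 for the last. No filter gave 266, 1100 and 14 for the ENMD-2076 comparisons and 1369 for the last. Fits of the 2 groups alone gave 813, 2503, 707, 3153, 2340 and 0 (edgeR, with 1737 at an unadjusted p under 0.05), and 668 between the compounds. Without both TAK901 2 µM libraries the first 4 were 953, 2460, 59 and 3970, and total-count scaling gave 1 for ENMD-2076 doses. In 4T1, pooling the DMSO libraries without the naming set, which adds the difference between the sets to the spread, gave 3101 for ENMD-2076 1.25 µM, 0 for TAK901 1 µM (edgeR, 1547 at an unadjusted p under 0.05), 47 for 2 µM, 0 between TAK901 doses (edgeR, 153 at an unadjusted p) and 10 for the overlap of compounds. TAK901 1 µM gave 2497 with the 2 groups alone, 3042 within its naming set and 542 thinned to 3746588 reads, and 2 µM gave 1451 thinned. TAK901 doses in 4T1 gave 56 with DESeq2, 81 without filter, 99 with the 2 groups alone, 77 within the naming set, 20 without both ENMD-2076 2.5 µM libraries, 5 thinned and 17 with total-count scaling. Leaving out 1 library, where the lone library left in a group is assumed to vary like the others, gave 11 to 966, 67 to 2420, 1 to 64, 739 to 3995, 2843 to 5594 and 22 to 3581 in the MDA-MB-231 order above, 861 to 4612 between compounds and 55 to 1786 for their overlap. In 4T1 it gave 6032 to 7393 and 10162 to 11305 for the ENMD-2076 doses, 10660 to 11563 between them, 376 to 1739 and 1245 to 2582 for TAK901, 1 to 34 between its doses, 8411 to 9616 between compounds, 293 to 711 for their overlap and 45 to 48 list tests. Signs turned for Aurka at ENMD-2076 2.5 µM with total-count scaling (-0.34), and with pooled DMSO for Hhex (-2.15) there and at TAK901 2 µM for Ccnb1 (0.12), Rrm2 (0.077), Mcm3 (0.070), Vsir (-0.69), Epha4 (0.26), Gpnmb (-1.45), Thbs1 (-0.46), Ndrg1 (-1.19), Aldoc (-0.93) and mt-Nd4 (-0.54), and for the DNA replication list at TAK901 1 µM (0.16). Apart from pooling, thinning and fewer groups or libraries, which change the spread or the depth by construction, the cause was not tested. The compounds in 4T1 could not be fitted with 2 groups alone, DESeq2 has no list tests, and the difference between the cell lines, by joined fit or z test, was not run for want of human names. At 3.75 M reads TAK901 2 µM in 4T1 limits genes under about 0.801 CPM.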

Other observations

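Markers of cell types that a culture should lack were few in the libraries labelled 4T1. Of 7 haematopoietic markers 2 rose at 1.25 µM ENMD-2076 and 1 rose and 1 fell at 2.5 µM (camera adjusted p = 0.170 and 0.770). The B cell receptor component Cd79a went from 0.0270 CPM in DMSO 1 and 2 to 6.78 CPM at 2.5 µM. With 2 µM TAK901 1 haematopoietic marker, Cd14, rose by 0.56 (list adjusted p = 0.0622, which passed with the 2 groups alone at 0.0167, within set 2 alone at 0.0174, without both ENMD-2076 2.5 µM libraries at 0.0317, without DMSO replicate 1 at 0.0364, without DMSO replicate 4 at 0.0347 and without TAK901 2 µM replicate 2 at 0.0414). Of 7 fibroblast markers 2 rose and 1 fell at 1.25 µM ENMD-2076 (0.327), with Postn, a matrix protein of fibroblasts, rising from 0.162 to 61.0 ± 4.18 CPM there. At 2.5 µM 1 rose and 1 fell (0.848), and with 2 µM TAK901 only Postn rose (list 0.914). That Postn call was lost with the replicate block (adjusted p = 0.0663), with the 2 groups alone (0.131) and with thinned counts (0.249). It was also lost without any 1 of the 4 libraries compared (log2 fold change 1.19 to 1.37). Of 6 endothelial markers 2 fell at 1.25 µM and 4 rose with 1 lower at 2.5 µM (median 2.84), where Esam rose from 0.143 to 3.31 CPM and Pecam1 from 0.172 to 1.63 CPM, and the list did not pass at either dose (0.345 and 0.651) or with TAK901 2 µM (0.939).

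Of the tests of the naming sets in this part, that of genes with pseudogenes was set before its result was seen and the others after. Many genes of the set 2 DMSO libraries labelled 4T1 were nearly absent from set 1: of 7743 genes at 20 CPM or more in set 2, 162 lay under 1% of that level in set 1, and of 7578 such genes in set 1, 5 did so in set 2. Those 5, named after their values were seen, were mt-Co2, mt-Atp8, mt-Atp6, mt-Co3 and mt-Nd3. For genes with near-identical copies, reads that align to several places and were counted in set 1 but left out in set 2 are a candidate explanation: 268 genes with a named pseudogene lay at a median of -0.271 on the log2 scale in set 2 against set 1, under every one of 10000 expression-matched random sets (lowest -0.198, permutation p = 1e-04, the smallest these draws can give). Gapdh, which has many such copies, stood at 1581 ± 4.45 CPM in set 1 DMSO and 103 ± 4.64 CPM in set 2 DMSO. Most of the 268 genes moved far less: 15.7% were lower by over 2-fold in set 2, against 11.7% of other genes. The random sets were matched on expression only, so the permutation p does not separate read counting from a difference between cells. Such counting does not account for the transcripts found in set 2 alone, since the set 2 DMSO library with fewer Y-linked reads still had 5941 while set 1 had 0.

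For those transcripts, cells in set 2 other than those of set 1 may be the source, from another label or a mixed culture: the highest summed Y-linked CPM over the lowest was 1.06 across the 6 set 2 libraries, with and without TAK901. The counts in both directions are in line with a mixture of such cells with those of set 1, which would leave few genes of set 1 near absent from set 2: 162 against 5 under 1% of the level, the 5 being mitochondrial genes with copies elsewhere in the genome, and 281 against 23 under 10%. Other cells alone that also express nearly all genes of set 1 are not excluded by these counts. Because 4T1 derives from a female mouse, the Y-linked reads in all 6 libraries of set 2 argue against 4T1 cells as their only source of RNA. They do not tell a mixture from other cells alone. Neither these reads nor their absence from set 1 was set against an outside reference of the 4T1 line. No biological explanation was tested, because the design names none that separates the sets. Other set 2 DMSO levels, chosen after their values were seen, were 50.3 CPM for Foxa2, 65.5 for Cldn18 and 27.6 for Krt20.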
